A study of Homo sapiens with 10 samples.

How the data were processed

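Kidney organoids were grown from the human induced pluripotent stem cell line CRL1502, clone C32, and 10 of them were profiled by RNA sequencing at day 18. Per the labels' protocols, cells received 8 uM CHIR99021, a GSK3 inhibitor that activates WNT signalling, for 4 days and then 200 ng/mL FGF9 with 1 ug/mL heparin for 3 days. They were pelleted, given 5 uM CHIR99021 for 1 h, kept in FGF9 and heparin for 5 days and moved to basal medium for 6 days. RNA was taken with a QIAGEN RNeasy micro kit and made into libraries by Illumina protocols, per the labels. The molecule is labelled total RNA. The ribosomal depletion or poly(A) step, the strandedness and the gene annotation are not given in the sources used here.

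The authors deposited raw read counts per gene symbol in a table of 42785 genes and 10 organoids. Per the submitters' processing notes, reads were processed with STAR 2.4.0h1 and featureCounts 1.4.6 on the hg19 build. No coordinate is printed here, since no annotation of that build was used. Reads of near-identical gene copies, such as histone, ribosomal protein and mitochondrial genes with nuclear copies, may have been split or lost in counting, and overlapping antisense genes cannot be separated without strand. Values of those genes are therefore uncertain.

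Samples were grouped by the batch in the labels. Batch 2 held 4 organoids from 1 vial of cells, and batch 3 held 6 organoids made at a later date from 3 vials, 2 organoids per vial. Total counts ran from 46.3 to 80.2 M in batch 2 and from 14.7 to 21.9 M in batch 3. The 21 pairs of organoids within a batch were compared by a chi-square statistic over genes with counts of at least 10, which gave 2.83 to 41.0 per degree of freedom, so no library was counted as a duplicate. The labels do not say that organoids of a vial came from separate cultures, so p-values measure the spread between these organoids.

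Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter and the two-sided quasi-likelihood test, and with Benjamini-Hochberg adjustment at 0.05. The batch fit had batch as its term and kept 17625 genes. The vial fit had 1 term per vial over all 10 organoids, so that batch 2 shared in the estimate of the spread, and kept 18603 genes. An F test asked whether the 3 batch 3 vials differed, and 3 contrasts compared pairs of vials. Log2 fold changes are given with a standard error computed as the fold change divided by the square root of its F statistic. Expression is given as CPM after TMM, as mean ± SD.

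The gene lists, 31 of them with 441 entries, were fixed before the data were examined: nephron progenitor, early nephron, podocyte, proximal tubule, loop of Henle and distal tubule, collecting duct and ureteric epithelium, epithelial, stroma, endothelial, neural, skeletal muscle, melanocyte and glia, cartilage, pluripotent stem cell, blood and immune, and 16 lists of processes and technical signs. Older symbols stood in for 3 entries and 1 entry had no row. Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Genes were named by a rule set before the data were examined. For the batches it took the 4 largest changes in each direction with non-overlapping CPM ranges and a CPM of at least 5, plus 1 or 2 members of each list with the smallest p. For the vials it took the 6 smallest F p with a CPM of at least 5 in the highest vial, and 2 members of each list that passed. For the spread between organoids it took the 5 largest variances over all genes and over the cell lists, among genes with a mean CPM of at least 5. Some genes that the rule took are not reported here. Genes outside that rule are named where marked as chosen after their values were seen.

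The distance between organoids was the root mean square difference of log2 CPM with a prior count of 2. It was tested by exact permutation over all 210 splits into 4 and 6 and over the 15 pairings of the batch 3 organoids. Variance per gene was split into batch, vial and organoid parts by nested moment estimates, which were summed over genes, with a jackknife standard error over organoids. Alternatives, listed before the data were examined unless marked otherwise, were RLE size factors, library size alone, no filter, a CPM filter, thinning of all libraries to 14743953 reads, DESeq2 1.42.0, limma-voom, a minimum fold of 1.5, vial as a random block, sums per vial, subsets of vials, leaving out each organoid, and other distances and variance estimators, among them lme4 1.1.37.

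The scripts were tested on simulated data with 200 changed genes and a raised cartilage list. Calls of that list's genes count as true. In the simulated batch comparison of 17250 genes, 82.1% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 7.51% of calls were false. In the simulated contrast of vial 3 with vial 1 over 17969 genes the shares were 65.7%, 86.6% and 100%, with 6.32% of calls false. The simulated F test over the same genes recovered 64.2%, 89.6% and 100%, with 4.79% false. Apart from the set changes, counts were drawn independently around 1 mean per gene, without spread between vials. The simulated vial comparison had no batch difference. Far fewer genes changed than between the real batches, where 71.3% of tested genes differed. The simulated shares therefore do not give the error rates of the real calls.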

Results

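RNA was sequenced from 10 human kidney organoids at day 18 of differentiation, structures grown from pluripotent stem cells that hold nephron, stromal and endothelial cell types. The study asked how reproducible the differentiation was. Batch 2 was 4 organoids made together from 1 vial of cells, and batch 3 was 6 organoids made later from 3 vials, with 2 organoids per vial. The batches differed in depth, with 59.4 ± 14.5 M counts per organoid in batch 2 (SD, n = 4) and 17.2 ± 2.64 M in batch 3 (n = 6), without overlap. The 28S ribosomal RNA gene RNA28S5 stood at 265 ± 56.2 CPM of the library in batch 2 and 2480 ± 1500 CPM in batch 3.

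Genes of the filtering and reabsorbing cells of the nephron were far lower in batch 3 than in batch 2, and the progenitor gene CITED1 and the pluripotency gene LIN28A were among the most increased. NPHS1, which encodes nephrin of the podocyte slit diaphragm, had 470 ± 49.3 CPM in batch 2 (n = 4) and 1.74 ± 0.248 CPM in batch 3 (n = 6), a log2 fold change of -8.09 ± 0.096 (SE, adjusted p = 2.39e-17). CITED1, a marker of uncommitted nephron progenitors, rose from 1.53 ± 0.251 to 98.3 ± 7.47 CPM (6.03 ± 0.10, adjusted p = 1.53e-15), and LIN28A, an RNA-binding protein of pluripotent and early embryonic cells, rose from 2.35 ± 0.378 to 162 ± 11.6 CPM (6.08 ± 0.098, adjusted p = 8.89e-16). Of 17625 genes tested with edgeR, 12561 differed between the batches (71.3%), 6165 higher and 6396 lower in batch 3, and 3637 of them differed by more than 2-fold, 1568 higher and 2069 lower.

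The other genes with the largest change were likewise taken only from genes whose CPM ranges in the batches did not overlap. DSC1, a desmosomal cadherin, fell by 8.96 on the log2 scale, from 139 ± 16.8 to 0.269 ± 0.167 CPM, and AFP, a fetal serum protein, fell by 8.68, from 45.8 ± 10.7 to 0.112 ± 0.0941 CPM. LRRC3B rose by 5.30 to 32.6 ± 12.7 CPM, and FGF18, a fibroblast growth factor, rose by 5.23 to 5.67 ± 1.06 CPM.

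**Figure D1:**
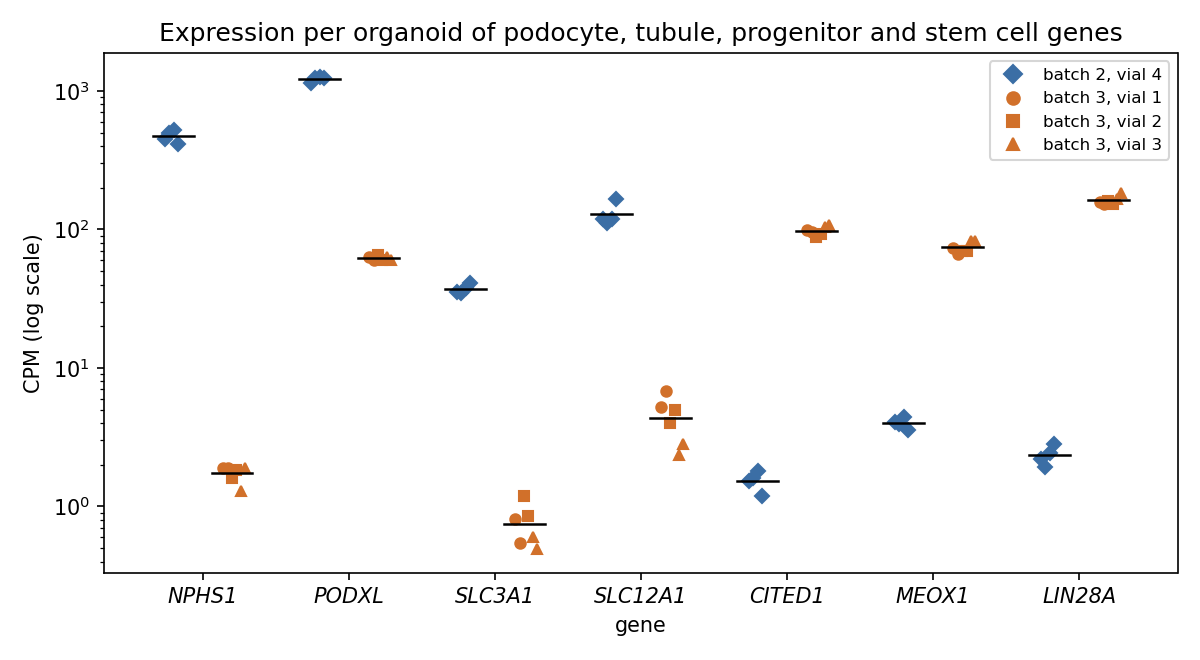
CPM on a log scale of 7 named genes in each organoid. Each point is an organoid, with its colour for the batch and its shape for the vial, and the lines are means. For every gene shown the 4 batch 2 and 6 batch 3 organoids do not overlap, with NPHS1 at 412 to 525 CPM in batch 2 and 1.3 to 1.91 CPM in batch 3. The naming rule required this of NPHS1, CITED1 and LIN28A.

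Of the 16 podocyte genes tested, 14 were lower in batch 3, with a list median of -3.78 (log2). The exceptions, named after their values were seen, were FOXC2, which was higher by 1.16, and COL4A3, which did not pass. The list differed from other genes with camera (adjusted p = 3.63e-49) and with an estimated correlation (adjusted p = 0.00076). PODXL, which encodes the podocyte surface sialoprotein podocalyxin, fell by 4.31 ± 0.044, from 1230 ± 52.0 to 61.9 ± 2.07 CPM. All 14 proximal tubule genes tested were lower, with a median of -3.45 (adjusted p = 0.0239 with an estimated correlation). SLC3A1, a subunit of the cystine transporter, fell by 5.65 to 0.748 ± 0.257 CPM, and the endocytic adaptor DAB2 fell by 2.37 to 19.5 ± 1.17 CPM.

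In the loop of Henle and distal tubule list 10 of 13 genes were lower and 2 higher, with a median of -1.83. SLC12A1, the sodium-potassium-chloride transporter of the thick ascending limb, fell by 4.91 ± 0.19, from 129 ± 25.4 to 4.38 ± 1.64 CPM, and KCNJ1, the potassium channel ROMK, fell by 5.21. The list passed with the preset correlation (adjusted p = 0.0205) and with fry (adjusted p = 0.000118), but not with an estimated correlation (adjusted p = 0.531). Of 9 collecting duct and ureteric genes, 5 were lower, among them AQP3 (-3.56) and KRT19 (-2.28), and 4 were higher (adjusted p = 0.0233, and adjusted p = 0.321 with an estimated correlation). The collecting duct call ended without batch 3 replicate 6 (adjusted p = 0.0506). Of 15 epithelial genes 9 were lower and 1 higher, with CDH16, a kidney cadherin, at -4.62 and ELF3 at -1.77 (adjusted p = 0.00728, and adjusted p = 0.531 with an estimated correlation). Counts of members over all genes and adjusted over the list alone were equal for these lists, except that 3 distal genes were higher over the list alone.

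The nephron progenitor list was divided, with 7 of 13 genes higher and 5 lower and a median of 0.919 (adjusted p = 2e-04, and adjusted p = 0.0886 with an estimated correlation). MEOX1, a mesodermal homeobox gene, rose by 4.21 ± 0.090, from 4.01 ± 0.350 to 74.1 ± 7.01 CPM. SIX2 (2.82) and GDNF (3.43) also rose, while DAPL1 (-6.09) and the posterior HOX genes HOXA11 (-2.65), HOXC11 (-3.19) and HOXD11 (-4.04) were lower; these 6 members were chosen after their values were seen. Of 13 early nephron genes 8 were higher and 4 lower, and the list did not pass (adjusted p = 0.208). CCND1, which encodes cyclin D1, rose by 2.12 to 1010 ± 82.3 CPM, while CDH6, a cadherin of the early tubule, fell by 2.27 from 719 ± 25.6 to 149 ± 14.3 CPM.

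Of 12 pluripotent stem cell genes measured, 7 passed the expression filter and all 7 were higher, with a median of 1.60 (adjusted p = 0.00212 with an estimated correlation). POU5F1 and NANOG were among those that did not pass the filter, so the list does not show that pluripotent cells remained. ZFP42, also known as REX1, rose by 2.35 to 67.7 ± 2.08 CPM. All 12 targets of FGF signalling were higher, with a median of 1.16 (adjusted p = 0.0103 with an estimated correlation), and the ETS factor ETV4 rose by 4.25, from 5.32 ± 0.629 to 101 ± 4.96 CPM. All 20 cell cycle genes were higher, with a median of 1.25 and CCNB2, a mitotic cyclin, at 1.57 (adjusted p = 0.0886 with an estimated correlation). All 13 replication-dependent histone genes were higher, with HIST1H2BD at 1.38 (adjusted p = 0.248 with an estimated correlation). Of 14 cholesterol synthesis genes 13 were higher, with FDPS at 1.3 (adjusted p = 0.147 with an estimated correlation). Of 15 genes of HOX groups 1 to 5, 14 were higher, with HOXC5 at 5.07 (adjusted p = 0.0667 with an estimated correlation). All 19 ribosomal protein genes were higher, with a median of 0.493 and RPS4X at 0.73 (adjusted p = 0.294 with an estimated correlation).

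Most stromal genes were lower in batch 3, while matrix genes went both ways. Of 16 stromal genes 14 were lower and 2 higher, with a median of -1.68, and the proteoglycan genes DCN and LUM had log2 fold changes of -5.93 and -4.46, with 0.326 ± 0.201 and 0.364 ± 0.180 CPM left in batch 3. That list passed with the preset correlation (adjusted p = 2.72e-05) and had adjusted p = 0.291 with an estimated correlation. Of 16 extracellular matrix genes 9 were lower and 3 higher, with the matrix glycoprotein gene SPARC down by 1.76 from 1910 ± 76.8 to 565 ± 42.5 CPM (adjusted p = 0.042, and adjusted p = 0.531 with an estimated correlation). The matrix call ended without batch 2 replicate 3 (adjusted p = 0.0667), batch 2 replicate 4 (0.0558) or batch 3 replicate 3 (0.0537), and with library size alone (0.0522). Of 12 targets of BMP and TGF beta 9 were lower and none higher, with CTGF at -4.06 (adjusted p = 0.168 with an estimated correlation). Of 13 genes of the unfolded protein and amino acid stress list 8 were lower, with DNAJB9 at -1.56 (adjusted p = 0.291 with an estimated correlation).

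**Figure D2:**
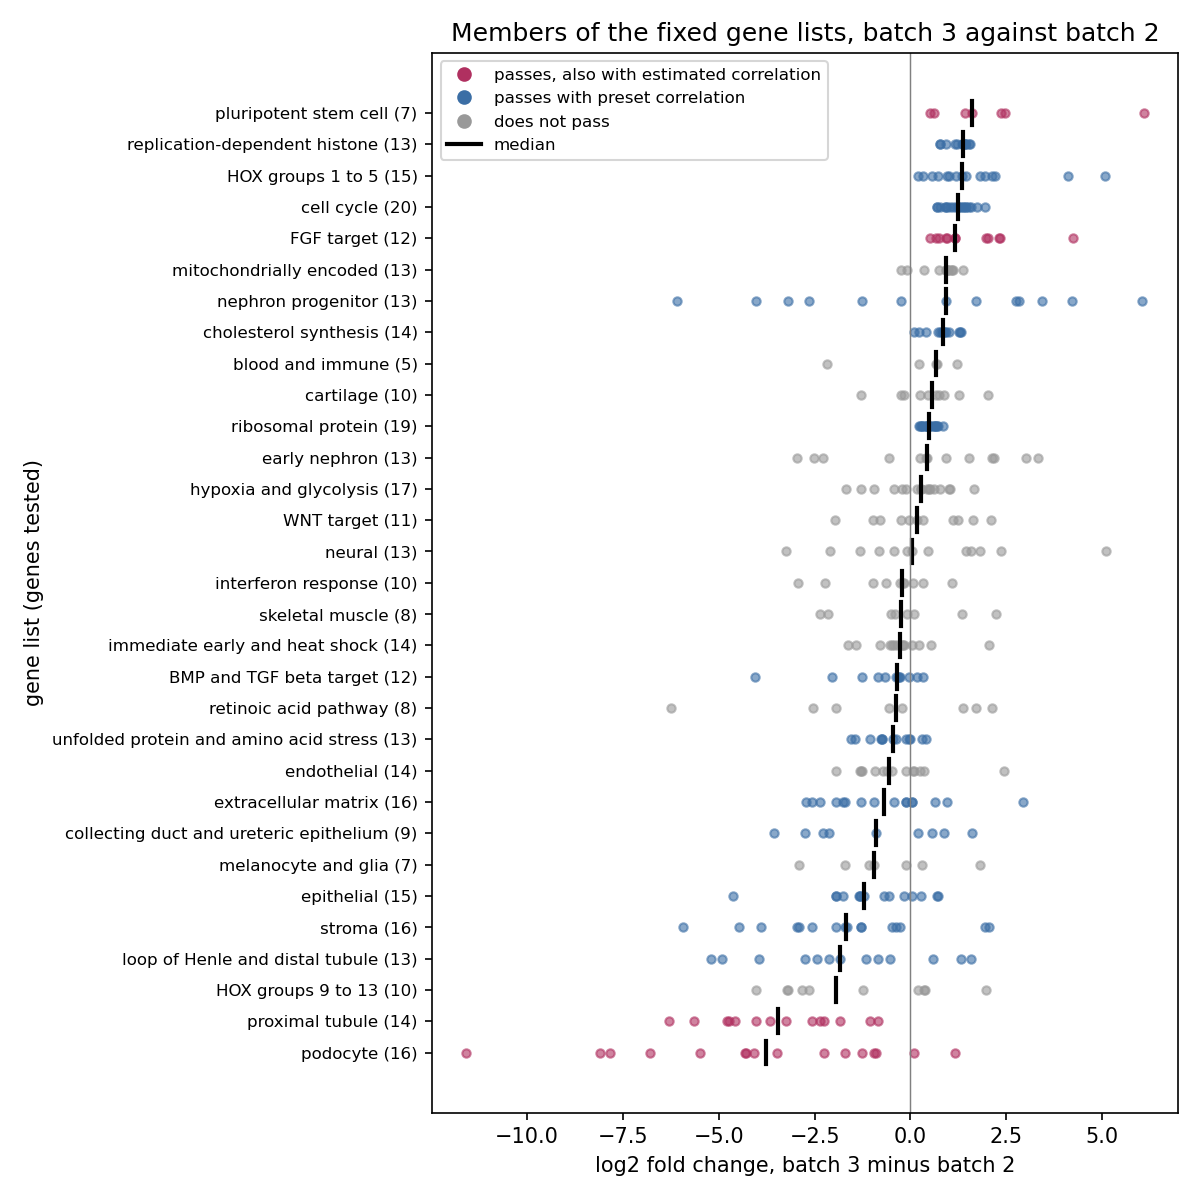
Log2 fold change, batch 3 minus batch 2, of each tested member of the 31 gene lists, with the number tested in brackets. Points are genes, black bars are medians, and colours show whether the list passed at adjusted p under 0.05. The podocyte and proximal tubule lists lie lowest, with medians of -3.78 and -3.45, and the pluripotent stem cell list highest, with 1.60.

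The remaining 14 lists did not pass with camera. Endothelial genes went both ways, with 8 lower and 3 higher of 14 (adjusted p = 0.211): ESAM fell by 1.93, while PLVAP, a protein of endothelial fenestrae, rose by 2.44 to 416 ± 78.4 CPM. Neural genes were divided, 6 higher and 5 lower of 13 (0.273), with NRN1 at 5.11 and HES6 at 2.36. In skeletal muscle (0.520) TNNI1 was at -2.37 and TNNT1 at 2.22, in melanocyte and glia (0.536) ERBB3 was at -2.90 and PMEL at 1.82, and in cartilage (0.306) COL11A1 was at -1.28 and COL2A1 at 1.27. The blood and immune list (0.788) had CD68 at -2.17 and FCER1G at 1.22, and its median of 0.67 and mean of 0.126 differed in sign from its test. Posterior HOX groups 9 to 13 (0.306) had 6 of 10 genes lower and 3 higher, with HOXB9 at 1.96. The retinoic acid list (0.787) held ALDH1A1, a retinaldehyde dehydrogenase that fell by 6.25 from 269 ± 33.9 to 3.57 ± 0.949 CPM. The hypoxia (0.424, EGLN3 at -1.29), immediate early (0.211, JUN at -1.62), interferon (0.208), WNT target (0.564, ZNRF3 at -0.97) and mitochondrially encoded (0.197, MT-ND3 at 0.93) lists also did not pass.

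Batch was confounded with depth and with the date of differentiation, and batch 2 came from a single vial, so a batch effect cannot be told from a vial effect on that side. The test against a fold of at least 1.5 called 4816 genes.

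Within batch 3, the organoids of vial 3 had lower epithelial genes (12 of 15) and higher stromal (10 of 16) and endothelial genes (7 of 14) than those of vial 1. Distal tubule genes were lower too (7 of 13), but that list did not pass with an estimated correlation (adjusted p = 0.0518). Against vial 2, 3 of 15 epithelial genes were lower in vial 3, and 4 of 16 stromal and 0 of 14 endothelial genes were higher. In camera with an estimated correlation the stromal list passed there (adjusted p = 0.0493), but not the epithelial (0.0659) or endothelial list (0.0964). GRHL2, a transcription factor of epithelial identity, fell from 12.7 ± 0.135 CPM in vial 1 to 2.60 ± 0.147 in vial 3 (log2 fold change -2.29 ± 0.187, n = 2 each, adjusted p = 7.97e-06), and the epithelial adhesion gene EPCAM fell from 74.2 ± 6.25 to 36.5 ± 4.47 CPM (-1.03 ± 0.106, adjusted p = 4.12e-05). PDGFRA, a receptor of stromal fibroblasts, rose from 19.9 ± 0.332 to 45 ± 3.73 CPM (1.17 ± 0.0924, adjusted p = 6.75e-06). The F test of edgeR found 642 of 18603 genes differing among the 3 vials (3.45%), and of these 522 also differed between the batches (81.3%, against 71.3% of all genes tested there). Vial 3 differed from vial 1 at 893 genes, 394 higher and 499 lower, and from vial 2 at 253, 75 higher and 178 lower, while vials 2 and 1 differed at 15, 11 higher and 4 lower.

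The 6 genes with the smallest F p differed most between vials 3 and 1. NRK, a kinase gene, rose from 13.8 ± 0.701 CPM in vial 1 to 26.4 ± 0.164 in vial 2 and 79.1 ± 7.26 in vial 3, with 314 CPM in batch 2. PAPPA2, a protease gene, fell from 175 ± 31.0 to 40.0 ± 6.03 CPM between vials 1 and 3 (-2.13 ± 0.140), with 114 ± 21.8 in vial 2. STAT4 (1.95 ± 0.153), BMPER (1.19 ± 0.0952), which encodes a BMP-binding protein, and PDGFRA were higher in vial 3, and the homeobox gene IRX3 was lower (-1.54 ± 0.119).

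Of 15 epithelial genes 12 were lower in vial 3 than in vial 1 and none higher, with a median of -0.835 (adjusted p = 0.0347 with an estimated correlation), and 13 were lower adjusted over the list alone. Of 13 loop of Henle and distal tubule genes 7 were lower, or 9 adjusted over the list alone, with a median of -1.12 (adjusted p = 3.27e-20 with the preset correlation, but 0.0518 with an estimated correlation). MAL, an apical membrane protein gene, fell by 2.16 ± 0.224. Against vial 2, MAL fell by 1.72 and IRX1 by 1.33, the latter with adjusted p = 0.0929 without batch 3 replicate 5. Neither the podocyte list (median -0.181, adjusted p = 0.513, with 1 gene higher and 1 lower of 16) nor the proximal tubule list (0.0263, adjusted p = 0.165, with 3 genes lower and none higher of 14) passed between vials 3 and 1.

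Of 16 stromal genes 10 were higher in vial 3 than in vial 1, or 12 adjusted over the list alone, with a median of 0.559 (adjusted p = 0.0297 with an estimated correlation), among them POSTN at 0.89 ± 0.0935. Of 14 endothelial genes 7 were higher, or 14 adjusted over the list alone, with a median of 0.561 (adjusted p = 0.0308 with an estimated correlation), with PLVAP at 0.62 ± 0.0828 and CDH5, which encodes VE-cadherin, at 0.62 ± 0.0859. Of 16 matrix genes 8 were higher, or 11 with 1 lower adjusted over the list alone (adjusted p = 0.0465 with an estimated correlation), and COL6A3 rose by 1.02 ± 0.0959 to 165 ± 1.53 CPM. Between vials 2 and 1, no stromal or endothelial gene passed over all genes, but 8 and 7 were higher adjusted over the list alone, and both lists passed (adjusted p = 0.0326 for each with an estimated correlation). The ribosomal gene RNA28S5 also differed between vials and was lowest in vial 3, though vial 2 did not lie between the others as in these lists, at 966 and 1012 CPM of the library in the organoids of vial 3, 2543 and 3067 in vial 1, and 5002 and 2309 in vial 2.

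**Figure D3:**
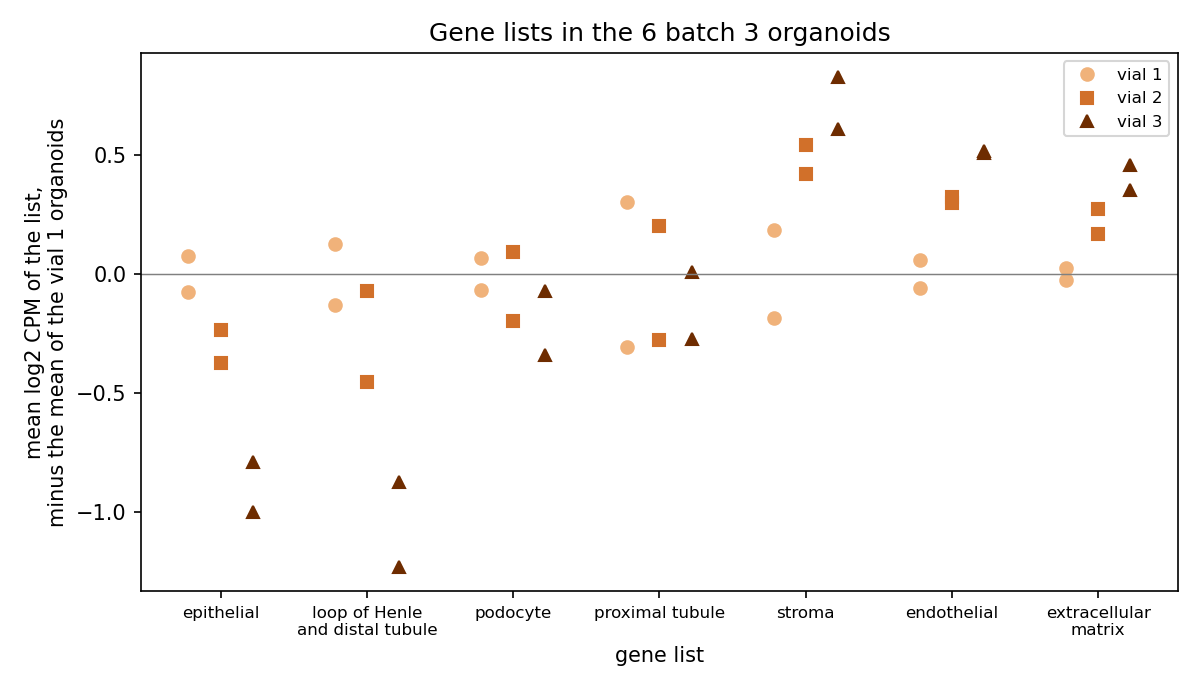
Mean log2 CPM of 7 gene lists in each of the 6 batch 3 organoids, minus the mean of the 2 organoids of vial 1. Points are organoids, with shape and shade for the vial. For the epithelial list both organoids of vial 3 lie below all 4 others, and for the endothelial list both lie above them.

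Other lists passed with the preset correlation but not with an estimated one between vials 3 and 1. HOX groups 9 to 13 had 5 of 10 genes lower, with HOXC10 at -1.85 and HOXA10 at -0.59 (adjusted p = 0.0964 with an estimated correlation), and HOX groups 1 to 5 had 3 of 15 lower, with HOXD1 at -0.64 and HOXB4 at -0.57 (0.231). The FGF target list had 4 of 12 higher, with DUSP4 at 0.58 and DUSP5 at 0.52 (0.0659), and the neural list 3 of 14 higher, with NEFM at 1.33 and NEFL at 0.83 (0.0964). Nephron progenitor genes went both ways, 2 higher and 2 lower of 13, with OSR1 at 1.29 and TMEM100 at 1.23 (0.230), as did early nephron genes, 1 higher and 3 lower of 13, with SFRP2 at 0.41 and PAX2 at -0.69 (0.200). In melanocyte and glia MITF was at -1.07 and ERBB3 at -0.83 (0.156), in collecting duct TFAP2A at -1.65 (0.095) and in cartilage HAPLN1 at 0.76 (0.160), while the cell cycle list had 1 of 20 genes higher (0.519) and the histone list none (0.431). Calls ended without a single batch 3 organoid for OSR1, TFAP2A and HOXA10 (replicate 2 or 5), PAX2 (1 or 5), SFRP2 (1, 2 or 6) and HOXD1 (5), and for the early nephron (1 or 5), nephron progenitor (2), melanocyte and glia (2 or 5), cartilage (2, 3, 4 or 5) and HOX 1 to 5 (6) lists. With the preset correlation the hypoxia and glycolysis list set vial 2 apart. It was higher in vial 2 than in vial 1 with that correlation (adjusted p = 1.4e-11), but not with an estimated one (0.104) or with fry (0.0902). In that contrast 0 of 17 genes passed over all genes, and 4 were higher adjusted over the list alone. The list did not pass between vials 3 and 1 (adjusted p = 0.328). It had 5 of 17 genes lower in vial 3 than in vial 2, with BNIP3 at -1.0 and NDRG1 at -0.63 (adjusted p = 0.110 with an estimated correlation). In the last contrast NDRG1 lost its call without batch 3 replicate 3, 4 or 5. In all, 41 of 93 tests of a list in a vial contrast passed, and 7 did so with an estimated correlation.

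The vial counts rested on single libraries. The F test gave 1305 genes without batch 2 replicate 4 and 197 without batch 3 replicate 5, and a fit on the batch 3 organoids alone gave 1903.

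Whole profiles were closer within a batch than between batches. The root mean square difference of log2 CPM was 0.25 ± 0.0433 over 6 pairs of batch 2 organoids, 0.389 ± 0.015 over 3 pairs from the same batch 3 vial, 0.422 ± 0.0334 over 12 pairs from different batch 3 vials and 1.11 ± 0.0337 over 24 pairs from different batches (SD over pairs, which share organoids). The excess between batches was 0.745 (exact permutation test, one-sided, p = 0.00476, the smallest that 210 splits allow). Between vials it was 0.0324 (exact permutation test, one-sided, p = 0.133, where 15 pairings allow no less than 0.0667), so a difference in whole profiles between vials could not have passed here. Every pair from the same batch 3 vial also joined a library with more MT-ND6 and olfactory receptor reads (replicates 2, 4 and 6) to 1 without. Replicates 2 and 4, from different vials, lay 0.360 apart, and replicates 1 and 2, from the same vial, 0.401. Mean Spearman correlations across genes were 0.9967 in batch 2, 0.9954 within batch 3 vials, 0.9934 between them and 0.9379 between batches. Libraries were deeper in batch 2 (59.4 ± 14.5 M counts) than in batch 3 (17.2 ± 2.64 M), and counting noise in low genes adds to these distances. The smaller distance within batch 2 therefore cannot be read as closer organoids.

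**Figure D4:**
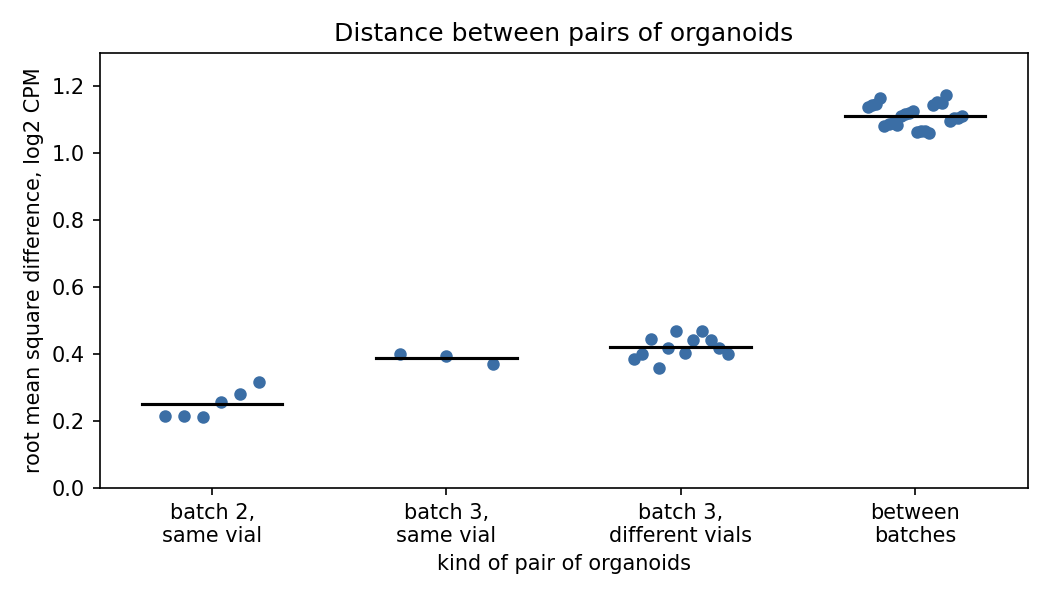
Root mean square difference of log2 CPM between pairs of organoids, by kind of pair, with points for pairs and lines for means. The 24 pairs between batches lie from 1.06 to 1.17, above every pair within a batch.

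Batch held 87.4 ± 1.61% of the summed variance of log2 CPM (jackknife SE), vials of batch 3 held 3.93 ± 2.60% and organoids of a vial 8.67 ± 2.13%. The jackknife left out single organoids, never a batch or a vial. Its SE therefore does not measure how the batch and vial shares would vary over other batches or vials. The shares describe these samples. Each batch 3 vial held 1 library with more MT-ND6 and olfactory receptor reads (replicates 2, 4 and 6), so the organoid part takes in that difference. That part also takes in counting noise of low genes, which is larger in the less deep batch 3 libraries. The organoid part is also subtracted in computing the vial part. The shares depended on the estimator, with 59.8% for batch, 11.2% for vials and 29.1% for organoids as means over genes by REML, and 80.6%, 1.91% and 17.5% as medians over genes. Batch was the largest part for 11906 of 17625 genes (67.6%), organoid for 3894 and vial for 1825. The batch share was 98.9% over the podocyte list and 98.7% over the pluripotent list, and the vial share was largest among the lists for the epithelial list, at 19.9%. ESRP1, an epithelial splicing factor, ran from 2.09 to 12.4 CPM in batch 3 and had a larger vial than batch component (0.929 and -0.517). The mitochondrially encoded list stood apart, with an organoid component of 50.5% of its total, beside 71.3% for batch and a negative vial estimate of -21.8%.

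Among genes with a mean CPM of at least 5, the gene that varied most between organoids of a vial was mitochondrial, MT-ND6, with a variance of 1.5. It was followed by DCN (0.923), TRPM3 (0.86), the mitochondrial MT-ND5 (0.757) and SLC5A8 (0.624). MT-ND6 ran from 17.3 to 128 CPM in batch 2 and from 58.3 to 235 CPM in batch 3, and MT-ND5 from 103 to 421 and from 226 to 667 CPM. DCN, TRPM3 and SLC5A8 had levels of 2.12 CPM or less in batch 3. Each of these genes and both mitochondrial ones were higher in batch 3 replicates 2, 4 and 6 than in their vial partners. Those 3 libraries also had more olfactory receptor reads, so this spread cannot be told from a difference between libraries. Among the cell lists LRP2, the proximal tubule receptor megalin, and CLDN16, a tight junction gene of the thick ascending limb, also ranked high, with variances of 0.31 and 0.139. In batch 3 LRP2 was at 0.833 to 2.38 CPM, again higher in replicates 2, 4 and 6 than in their vial partners. CLDN16 was at 0.417 to 1.43 CPM there, and in batch 2 at 24 CPM in replicate 4 against 12.7 to 15.5. Low counts and differences between libraries therefore enter both variances.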

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

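The tests chosen after the result was seen were the comparison of the progenitor and early nephron lists with the podocyte and proximal tubule lists, that of MT-ND6 with other mitochondrial genes, the limit of 1 CPM in the comparison of vials, and the counts without 4 libraries or with a term for them. The other tests were written down before their own values were seen.

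Over 178 sets of values within a batch, 9 had a sample far from the others by Dixon's criterion, where chance gives about 8.9. In batch 2 replicate 4, 35300 genes had reads (29700 to 30300 in the others), AFP had 61.9 CPM (39.2 to 41.4), SLC12A1 167 CPM (112 to 120) and KCNJ1 14.9 CPM (9.39 to 9.95). RPS4X had 1490 CPM in batch 2 replicate 1 (1600 to 1620 in the others), and the extracellular matrix list a mean log2 CPM of 6.57 in batch 2 replicate 3 (6.46 to 6.48). In batch 3 the cartilage list had a mean log2 CPM of 4.37 in replicate 5 (4.08 to 4.15), the BMP and TGF beta target list 5.22 in replicate 1 (5.35 to 5.39), and HOXC5 11.1 CPM in replicate 2 (15 to 16.4).

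The podocyte and proximal tubule lists were far lower in batch 3, which was also sequenced less deeply. With all libraries thinned to equal totals the median log2 fold change of their 28 tested members was still -3.71 (95% bootstrap interval over genes -4.66 to -2.36). Thinning keeps each gene's expected share of reads, so it could hardly move this median and does not decide on depth. After a trend on gene length and GC content was removed the median was -3.41 (-4.42 to -2.11, 30 genes). The trend took 0.623% of the variance of log2 fold change over genes, so it accounts for little of the difference. A lower share of all nephron lineage cells would lower progenitor and early nephron genes too, but the median of those lay 4.25 above that of the podocyte and proximal tubule genes (2.21 to 5.99). Of 9 genes that fall with developmental age in many tissues, such as LIN28B, 8 were higher in batch 3 and ARID3A did not pass. The median of the 9 was 0.64 (0.13 to 1.5). This goes with the hypothesis that the batch 3 organoids were less advanced at the same day, but does not establish it. Those genes were chosen after the batch differences in cell type genes were known, among them the rise of LIN28A (6.08). Several of the 9 belong to the LIN28 and IGF2BP group, so their rise may not be evidence separate from that of LIN28A. The bootstrap interval took the 9 genes as independent. Nephron progenitor genes were divided, with 7 higher and 5 lower of 13. A difference between library or sequencing batches cannot be told apart from the batches of differentiation, since no label separates them.

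In vial 3 the epithelial and distal tubule lists were lower than in vial 1, though the distal list did not pass with an estimated correlation (adjusted p = 0.0518, against 0.0347 for the epithelial list). Thinned to equal totals, their median was -0.91 (-1.18 to -0.63, 28 genes), but thinning keeps each gene's expected share of reads, so this does not decide on depth. A lower share of all nephron epithelium would lower podocyte and proximal tubule genes alike, and 3 of 14 proximal tubule genes were lower. Over all tested members, however, the median of those lists was -0.06 against -0.90, a difference of 0.84 (0.28 to 1.19, 58 genes). Among members with at least 1 CPM it was 0.01 against -0.90, a difference of 0.91 (0.15 to 1.28, 47 genes). In batch 3 NPHS1 (1.74 CPM) and SLC3A1 (0.748 CPM) were near the floor, while PODXL (61.9 CPM) and DAB2 (19.5 CPM) were not. Both lists were far lower than in batch 2 and measure nephron epithelium in batch 3 poorly. The differences therefore do not exclude a lower share of all nephron epithelium. A difference limited to distal and ureteric-type epithelium, which may arise from the starting vial or from handling, stays open and untested.

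MT-ND6 and the olfactory receptor genes had more reads in the higher-numbered organoid of each batch 3 vial and in batch 2 replicate 4. The same 4 libraries had reads of more genes, in batch 3 29739, 31814 and 29781 against 26314, 27731 and 28476 in their vial partners. Small structural RNAs took a smaller share of their counts, 2.992 to 3.078% against 3.296 to 3.337% in batch 3. In batch 2 that share was 3.431% in replicate 4 against 4.309 to 4.529% in the others. The olfactory receptor sum of 413 genes was 29.5, 43.4 and 31.9 CPM in batch 3 replicates 2, 4 and 6, against 13, 19.3 and 18.2 in their vial partners, and 21.6 CPM in batch 2 replicate 4 against 8.75 to 11.2. Whether higher mitochondrial expression accounts for it stays open. MT-ND6 exceeded the median of 5 abundant mitochondrial mRNAs by at least 1.61 (log2) in all 4 comparisons, but that of all 12 other mitochondrial mRNAs by at least 0.96, under the bound of 1. MT-ND5 rose by 1.11 to 1.43 and MT-CYB by 0.79 to 1.11, while MT-CO3 was at -0.15 to 0.01. Carry-over of genomic DNA may account for it, and the summed CPM of 188 genes of other families that organoids are not known to use was also higher in all 4, but the lowest log2 ratio was 0.18, under the 1.2-fold set beforehand, so this stays undecided. Without these 4 libraries 11911 genes differed between batches and 401 among vials, the latter with 1 organoid per batch 3 vial and all spread from 3 batch 2 organoids, while a term for them gave 12655 and 962.

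For the batch comparison, 1 of 100 splits of the 10 organoids drawn at random, the real one included, gave as many genes, 12561 against a highest other of 336. Every other split mixed the batches, so the batch difference entered its spread and held its count down. The splits also took organoids as independent, though batch 2 came from 1 vial. This comparison therefore does not exclude chance on its own. For the gene lists 1 of 100 splits gave as many, 17 against a highest other of 16, a margin too small to exclude chance. The other splits gave 3 to 16 lists with a median of 11, so a list that passed with the preset correlation alone is weak evidence of a batch difference. For the vials 1 of 15 pairings gave as many, 642 genes against a highest other of 320, and 15 pairings are too few for a share under 0.05. The pairing with 320 genes kept both vial 3 organoids together and exchanged those of vials 1 and 2.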

How the results depend on the processing

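The counts without 4 libraries and with a term for them, and the counts without ribosomal and small structural RNAs, were chosen after seeing the data. The batch gene count stayed within 1.5 times of 12561 under every alternative run except the test against a 1.5-fold change, which gave 4816, since it asks for a larger change; without 1 organoid it ranged from 11894 to 12514. It was 10030 with counts summed per vial, where batch 2 is a single sum and all spread comes from batch 3, so that count says little of stability. It was 11483 with thinned libraries, where 11279 of the same genes were called, and the share higher in batch 3 was 49.4%. That share was 44.7% with library size alone and 36.1% of 14242 genes with no filter. Without ribosomal and small structural RNAs it was 12481. The 17 batch lists became 4 with an estimated correlation and 30 with fry, and 16 to 17 without 1 organoid. Same-numbered organoids of the batches had correlations of 0.0702, -0.0347, -0.0352 and 0.232, so the numbers did not pair them, and a replicate block gave 12066 genes and 19 lists.

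Vial counts moved more. The F test gave 1122 genes with no filter, 337 with limma-voom, 1903 on batch 3 alone, 401 without the 4 libraries, 962 with a term for them and 197 to 1305 without 1 organoid. Vial 2 against vial 1 gave 127 with no filter, 55 with DESeq2, 165 on batch 3 alone, 1 without the 4 libraries, 44 with a term for them, 0 with limma-voom (803 at an unadjusted p under 0.05) and 0 for a 1.5-fold change (139 unadjusted), against 15 with edgeR (1165 unadjusted); without 1 organoid it ranged from 0 to 57. Vial 3 against vial 1 gave 84 for a 1.5-fold change, 533 with limma-voom, 2098 on batch 3 alone, 488 without the 4 libraries, 1175 with the term and 340 to 1505 without 1 organoid. Vial 3 against vial 2 gave 519 with no filter, 8 for a 1.5-fold change, 381 with DESeq2, 122 with limma-voom, 1274 on batch 3 alone, 417 with the term and 52 to 706 without 1 organoid. The highest of each range came without batch 2 replicate 4 (1305, 57, 1505 and 706 genes) and the lowest of those above 0 without batch 3 replicate 5 (197, 340 and 52); the F count was also 366 without batch 3 replicate 1, 287 without replicate 2 and 356 without replicate 6. Without the 4 libraries each batch 3 vial kept 1 organoid, so all spread came from 3 batch 2 organoids. A lone organoid left in a vial was taken to vary like the others, and the cause of these shifts was not tested. The 41 vial list calls became 7 with an estimated correlation and 24 with fry, and ranged from 36 to 46 without 1 organoid.

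The distance between vials beyond that within them was -0.0167 with no filter, where genes with few reads enter. The batch share of variance was 85.6% with a prior count of 0.5, 90.5% with the CPM filter, 80.6% as a median over genes and 59.8% as a mean of shares per gene by REML. The organoid share was 5.96%, 17.5% and 29.1% under the last 3, and the vial share was 1.91% as a median over genes and 11.2% under REML, which weighs each gene equally. Named batch genes kept direction and call in 1577 of 1578 alternatives, with FCER1G lost without the 4 libraries; named vial genes did so in 894 of 1002 and vial lists in 554 of 656. No named gene changed sign. List medians changed sign for melanocyte and glia (0.135 without batch 3 replicate 2 between vials 3 and 1, and 0.00321 without replicate 4 between vials 3 and 2), for mitochondrially encoded genes between vials 2 and 1 (0.112 without replicate 2 and 0.219 without replicate 3) and for HOX 9 to 13 between vials 3 and 1 (0.009 with no filter), and melanocyte and glia was at 0 without the 4 libraries. Depth was lower in batch 3, which limits its low genes.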

Other observations

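All tests in this part were written down before their values were seen, though after the batch differences in cell type genes, LIN28A included, were known.

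Genes of the LIN28 and IGF2BP group, RNA-binding proteins of fetal and embryonic cells, were higher in batch 3 than in batch 2. TRIM71, a partner of LIN28 in early embryos, rose by 1.64 ± 0.06 on the log2 scale (SE, n = 4 and 6, adjusted p = 3.26e-12), from 58.2 ± 3.91 to 181 ± 11.2 CPM. LIN28B rose by 1.5 ± 0.05, from 102 ± 5.26 to 288 ± 14.7 CPM, and IGF2BP1 by 1.17 ± 0.05, from 205 ± 10.5 to 462 ± 20.7 CPM. IGF2BP3 (0.76), MYCN (0.64), IGF2BP2 (0.62) and ARID3B (0.56) rose by less, HMGA2 rose by 0.13 (adjusted p = 0.0306), and ARID3A was at -0.03 (adjusted p = 0.516).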
